A study of Homo sapiens with 9 samples.

How the data were processed

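RNA was measured in OCI-Ly1 cells after 48 h with DMSO, 150 nM JIB-04 or 500 nM JIB-04, with 3 libraries per group. Groups and replicate numbers come from the sample titles. Total RNA was depleted of ribosomal RNA, per the labels' protocols. The deposited values are raw counts of reads per gene symbol, 1 column per library, for 25370 symbols. The submitters' processing notes name TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6 and Subread, and the genome builds hg19 and mm10, without saying what each was used for. The annotation version and the strand setting are not given in the sources used here. No coordinates are given, because the table holds symbols and the reference used here is of another build (GRCh38), which served for gene names, transcript length and GC content. Of the members of the gene lists, 6 were matched through another symbol of the RefSeq gene table. Reads of near-identical genes, pseudogenes or overlapping genes can be split or lost in such counting, which can affect histone, ribosomal protein and metallothionein genes.

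The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 15089, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 9 libraries, so that the 3 groups share an estimate of the spread, and the 3 pairwise contrasts and a test over any of the 3 groups were made. P-values were adjusted by the Benjamini-Hochberg method over genes, and a gene was called at an adjusted p under 0.05. Unless another tool is named, adjusted p-values of genes come from edgeR's quasi-likelihood test, and those of lists from limma's camera. Standard errors of log2 fold changes were derived from the quasi-likelihood test, as the unshrunk change divided by the square root of F. The log2 fold changes themselves are shrunk slightly by a prior count, so for genes with few counts in a group the errors are approximate. Values in CPM are edgeR's counts scaled to library size after TMM normalization.

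The 32 gene lists were fixed before the data were examined, as were the main design and most alternatives. Lists of at least 4 tested members, 30 in all, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The estimated-correlation form of the same test and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, were alternatives. Genes are named by a rule fixed before the data were examined. It takes 10 fixed genes, whether called or not. It takes the 6 largest increases and 6 largest decreases at each dose against DMSO, and 3 of each for 500 against 150 nM, among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries. For each list that is called, or of which at least 1 of 3 tested members is called, it takes up to 3 members with the smallest adjusted p in the direction of most called members and 1 in the other direction. The text gives some of these members, and ZWILCH was named outside the rule. Symbols of unnamed loci and of small or clone-named RNAs were left out of the largest changes.

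Alternatives were DESeq2 1.42.0 with its size factors, limma-voom, scaling by DESeq2's size factors or by total counts, no filter, a filter of 1 CPM in 3 libraries, fits of only the 6 libraries compared, the replicate number as a block, leaving out each library in turn, and leaving out the 20 most abundant genes. Chosen after the data were seen were thinning every library to the smallest total, and offsets that hold each library's lowess trend (span 0.3) on the GC content or the length of each gene's longest transcript, which 95.5% of tested genes have. The agreement of the doses was set beside simulated unchanged groups that share the DMSO libraries. It was also measured, after the data were seen, with 1 DMSO library as control of one dose and the other 2 as controls of the other dose.

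The fits were tested on simulated counts with 200 changed genes, drawn only from genes above a minimum mean count. The shares recovered hold for such genes and not for all tested genes. For 150 nM against DMSO, with 14522 genes tested, 42% of genes changed 1.25-fold, 80% changed 1.5-fold, 88% changed 2-fold and 100% changed 4-fold were recovered, with 10 false calls among 165. For 500 nM against DMSO, with 14528 genes, the shares were 42%, 80%, 96% and 100%, with 11 false calls among 170. The simulated counts held no GC trend between libraries, so these false calls do not measure those of the real comparisons. Depth ran from 28476845 to 57198613 counts per library. Reads carry no molecular identifiers here, so counting intervals cover counting error only. Pairs of libraries of a group differed by more than sampling noise, with chi-square values per degree of freedom of 6.59 to 16.05, so all 9 were kept as separate libraries.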

Results

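RNA sequencing of ribosomal RNA-depleted total RNA was available for OCI-Ly1, an established human cell line derived from diffuse large B-cell lymphoma. Cells were cultured for 48 h with the vehicle DMSO, with 150 nM JIB-04 or with 500 nM JIB-04, and 3 libraries were made for each condition, 9 in all. JIB-04 is a small-molecule inhibitor of Jumonji-domain histone demethylases, the enzyme family to which KDM4A and KDM4C belong. The deposited table held 25370 gene symbols, with 28476845 to 57198613 counts per library. DMSO replicate 2 was the shallowest library, and the 500 nM libraries held 42351389 to 57198613 counts. The filter on low counts left 15089 genes for testing. Libraries of one group correlated at r = 0.987 to 0.9932 across genes. Pairs from different groups correlated at r = 0.9584 to 0.9912, so the ranges overlapped. The highest of these pairs was DMSO replicate 1 with 150 nM replicate 1. The first principal component held 59.4% of the variance and placed the 500 nM libraries (53.3 to 59.7) apart from DMSO (-43.4 to -34.1), with 150 nM between (-22 to -16.9). DMSO replicate 2 stood apart on the second component, at -42.4. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

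The first comparison asked which transcripts changed at the lower dose. At 150 nM JIB-04, genes of the amino-acid and integrated stress response rose above DMSO. CHAC1, a glutathione-degrading enzyme induced by ATF4, rose from 4.69 to 15.5 CPM (counts scaled to library size), a log2 fold change of 1.72 ± 0.11 (SE, n = 3 per group, adjusted p = 1.13e-11). PSAT1, an enzyme of serine synthesis, rose by 0.84 ± 0.06 on the log2 scale, and SESN2, a stress-induced regulator of mTORC1, by 1.12 ± 0.07. Of the 32 tested members of the ATF4 list, 24 rose and none fell (31 rose when adjusted over the list alone), with a median log2 fold change of 0.389. The list test gave an adjusted p of 2.17e-115, and the adjusted p was 0.00117 with an estimated correlation.

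The genes with the largest increases at 150 nM included SPNS3 (log2 fold change 2.34 ± 0.16), the NKG2D ligand gene ULBP1 (1.79 ± 0.17), the glycine transporter gene SLC6A9 (1.69 ± 0.15), SH3BP2 (1.20 ± 0.14) and the transcription factor gene CEBPB (1.14 ± 0.12). The largest decreases were those of PFKFB4, a regulator of glycolytic flux (-1.71 ± 0.22), the adenylate kinase gene AK4 (-1.28 ± 0.23), TSPAN11 (-0.93 ± 0.14), NRN1 (-0.84 ± 0.19), the cytochrome P450 gene CYP1A1 (-0.55 ± 0.10) and the antimicrobial peptide gene CAMP (-0.50 ± 0.13, adjusted p = 0.0487). NRN1 was not called without DMSO replicate 2 or 3 or 150 nM replicate 2 or 3 (adjusted p = 0.0737 to 0.143), by limma-voom (0.0739) or with GC trends removed (0.0663). CAMP was not called without DMSO replicate 1 or 2, any 150 nM library, or 500 nM replicate 1 or 3 (adjusted p = 0.0542 to 0.258), nor under 5 other alternatives (0.0506 to 0.0842). In total 144 genes rose and 48 fell at an adjusted p under 0.05. Of these, 37 rose and 4 fell by at least 2-fold. The libraries of the 2 groups did not overlap for 13.7% of tested genes, where chance gives 10%.

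Among p53 target genes, 4 of 25 rose at 150 nM and none fell (12 and 3 when adjusted over the list alone). They included the cell-cycle inhibitor gene CDKN1A (1.14 ± 0.07) and the pro-apoptotic gene BBC3 (0.93 ± 0.12). The list test gave an adjusted p of 1.28e-16, and the adjusted p was 0.00117 with an estimated correlation. SESN2 is in this list and in the ATF4 list. Of 17 glycolysis genes, 8 fell (13 when adjusted over the list alone), among them PGK1 (-0.29 ± 0.05), TPI1 (-0.29 ± 0.05) and PKM (-0.28 ± 0.05). Of 27 replication-dependent histone genes, 8 fell (20 when adjusted over the list alone), among them HIST1H1B (-0.23 ± 0.05), which was not called without DMSO replicate 1 or 2 or 150 nM replicate 2 or 3 (adjusted p = 0.0572 to 0.143), or in the fit of the 6 libraries compared (0.0598). The list tests gave adjusted p = 2.93e-20 for glycolysis and 7.76e-20 for histones, against adjusted p = 0.0891 and 0.142 with an estimated correlation. Both lists were also called lower when DMSO replicate 3 and 150 nM replicate 1 exchanged groups, at adjusted p = 0.000226 and 1.31e-12, and adjusted p = 0.573 for each with an estimated correlation. The exchange leaves the other libraries of both groups in place, so it keeps part of a dose effect. These calls therefore do not show that the labelled calls are unspecific.

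In all, 3 of 30 tested lists were called higher at 150 nM and 10 lower. Of the 3 called higher, homologous recombination and DNA repair had 1 of 26 members called (EXO1, 0.25 ± 0.05, and adjusted p = 0.0506 without DMSO replicate 2), with adjusted p = 0.41 with an estimated correlation. The other lists called lower had at most 1 member called. LDHA (-0.28 ± 0.05) was the member called among MYC targets and ribosome biogenesis, with adjusted p = 0.058 without 150 nM replicate 2. LDHA is in the glycolysis list too. PLK1 (-0.28 ± 0.07) was called among G2 and mitosis genes, though not without DMSO replicate 2 or 150 nM replicate 2 or 3 (adjusted p = 0.102 to 0.258), or in the fit of the 6 libraries compared (0.0654). PFKFB4 was called among hypoxia-inducible factor targets. By edgeR no member was called among 33 ribosomal proteins, 30 oxidative phosphorylation, 16 heat-shock, 27 cholesterol synthesis and 21 B-cell receptor signalling genes, where 3, 2, 7, 11 and 5 members had an unadjusted p under 0.05. DESeq2 called 1 cholesterol gene and limma-voom 2 heat-shock genes, and otherwise both called 0. Adjusted over the list alone, 5 heat-shock, 7 cholesterol, 3 G2 and mitosis, 3 hypoxia-inducible factor and 2 B-cell receptor genes fell. With an estimated correlation the adjusted p of these 8 lists lay between 0.0591, for cholesterol synthesis, and 0.576, for ribosomal proteins. With DMSO replicate 3 and 150 nM replicate 1 exchanged between the groups, MYC targets, cholesterol synthesis, ribosomal proteins and oxidative phosphorylation were also called lower (adjusted p = 0.0135, 0.0135, 1.74e-05 and 0.0152), and DNA repair genes higher (0.00018), with adjusted p = 0.573 for each of the 5 with an estimated correlation. That exchange also called G2 and mitosis genes higher (adjusted p = 0.0406, and 0.759 with an estimated correlation), opposite to the labelled groups. The exchange keeps part of a dose effect, so calls in the labelled direction do not tell such an effect from other differences between libraries. Calls were lost for B-cell receptor genes without DMSO replicate 1 or 150 nM replicate 2 (adjusted p = 0.0506 and 0.127), for G2 and mitosis genes without DMSO replicate 3 or 150 nM replicate 1 (0.088 and 0.176), and for hypoxia-inducible factor targets without DMSO replicate 3 (0.1). They were lost for ribosomal proteins without DMSO replicate 1 or 2 or 150 nM replicate 2 (adjusted p = 0.193 to 0.281), with GC or length trends removed (0.359 and 0.277), with total-count scaling (0.0898) and in the fit of the 6 libraries compared (0.0565). They were lost for oxidative phosphorylation without DMSO replicate 1 or 2 or 150 nM replicate 2 or 3 (adjusted p = 0.0574 to 0.256). Oxidative phosphorylation was not called either with GC or length trends removed (0.0534 and 0.252), with total-count scaling (0.0898) or DESeq2's size factors (0.0505), without a filter (0.0508) or in the fit of the 6 libraries compared (0.057). The DNA replication list was called higher with GC trends removed (adjusted p = 0.0447). Aryl hydrocarbon receptor targets, not called with all 9 libraries (adjusted p = 0.0802), were called lower without DMSO replicate 2 (0.021) or 150 nM replicate 3 (0.035). In the main design, the DNA replication and aryl hydrocarbon receptor lists each had adjusted p = 0.41 with an estimated correlation.

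Of 25 Jumonji demethylases and related hydroxylases, edgeR called 0 at 150 nM, DESeq2 1 and limma-voom 0, and 2 had an unadjusted p under 0.05 (1 rose and 1 fell when adjusted over the list alone). KDM4A (0.03 ± 0.07), KDM4B (-0.15 ± 0.09), KDM4C (0.01 ± 0.06) and KDM5A (0.00 ± 0.05) had adjusted p of 0.925, 0.627, 0.974 and 0.999. Without 150 nM replicate 1, KDM4B was called lower (-0.30, adjusted p = 0.0435). JMJD1C, not called here (0.18 ± 0.06, adjusted p = 0.146), was called higher without a filter (0.19, adjusted p = 0.0324), with the replicate number as a block (0.18, 0.0498) and with GC trends removed (0.14, 0.0388). It was also called higher without DMSO replicate 3 (0.24, adjusted p = 0.0207) or 150 nM replicate 1 (0.22, 0.0139).

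The count of 192 genes at 150 nM depended on single libraries. It was 107 without DMSO replicate 2, 98 without 150 nM replicate 2 and 545 without 150 nM replicate 1. With each library's trend on transcript GC content removed, an alternative chosen after the data were seen, 361 genes were called, 189 of them among the 192.

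The second comparison asked which transcripts changed at 500 nM JIB-04. Genes of the integrated stress response rose further, and all 32 tested members of the ATF4 list were higher than in DMSO, with a median log2 fold change of 1.472 (adjusted p = 2e-110, and adjusted p = 0.00333 with an estimated correlation). CHAC1 rose by 4.52 ± 0.10 on the log2 scale to 108 CPM, SESN2 by 3.64 ± 0.07 and PPP1R15A, which directs dephosphorylation of eIF2α, by 3.16 ± 0.08. Replication-dependent histone genes fell as a group, 27 of 27, with a median of -1.334 (adjusted p = 2e-92, and adjusted p = 0.00602 with an estimated correlation). HIST1H1B fell from 2633 to 641 CPM, a log2 fold change of -2.04 ± 0.05. HIST1H1C (-1.70 ± 0.05) and HIST1H2BJ (-1.69 ± 0.05) fell alike. Some histone genes of the same family are near-identical in sequence, so counts of single members can be uncertain.

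**Figure D1:**
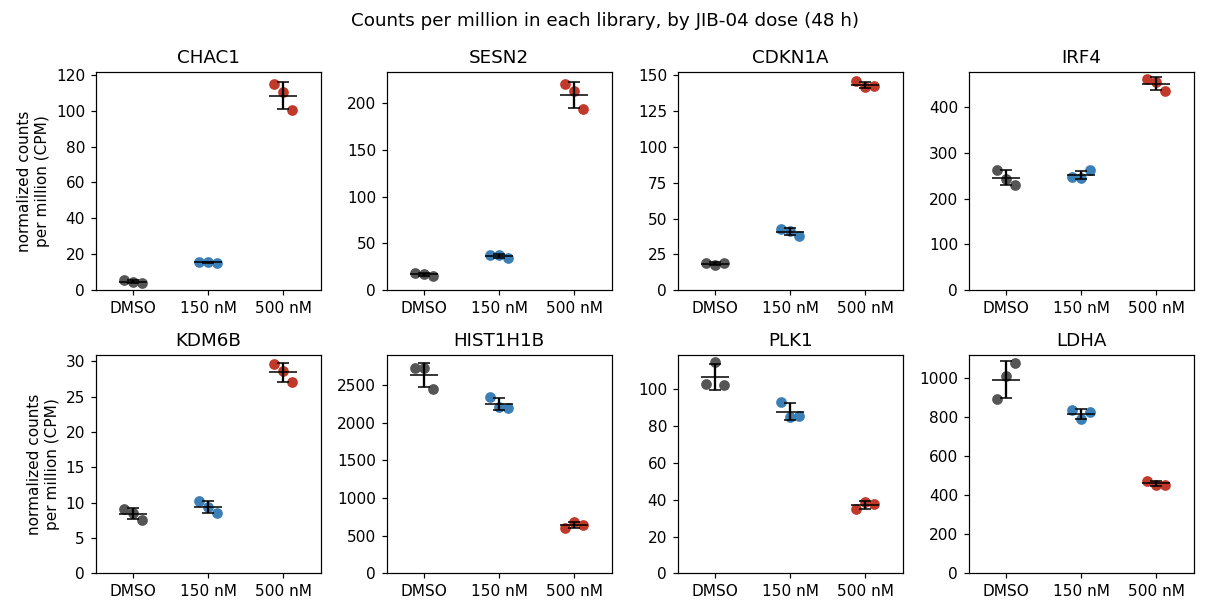
Normalized counts in CPM (vertical axes, each from 0) of 8 genes in each library, by JIB-04 dose, with points for libraries and black bars for the mean ± SD of 3 libraries. CHAC1 has means of 4.69, 15.5 and 108 CPM in DMSO, 150 nM and 500 nM, and HIST1H1B has 2633, 2251 and 641 CPM.

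In total 3975 genes rose and 3868 fell at 500 nM, of which 1106 and 439 changed by at least 2-fold. The called genes were 52% of the 15089 tested. Libraries of the 2 groups did not overlap for 59.2% of tested genes, where chance gives 10%. A list with near 52% of its members called does not stand out from other genes by that count. FAM129A had 2 counts over the 3 DMSO libraries and 4665 over the 3 libraries at 500 nM, a ratio of 1661 with an exact 95% counting interval of 460 to 13718. Other large increases were those of the splicing regulator gene ESRP1 (8.23 ± 0.26), the purinergic receptor gene P2RX1 (7.31 ± 0.29), KLHDC7B (6.61 ± 0.41), ASS1, which makes argininosuccinate (6.34 ± 0.23), and FERMT2 (6.13 ± 0.29). The largest decreases were those of PNMAL1 (-3.22 ± 0.24), CAMP (-2.65 ± 0.14), LGALS14 (-2.49 ± 0.19), the Fc receptor-like gene FCRL2 (-2.42 ± 0.09), CYP1A1 (-2.23 ± 0.10) and the antisense RNA gene IFNG-AS1 (-2.22 ± 0.12). The strand setting of the counting is not given in the sources used here, so IFNG-AS1 counts can include reads of an overlapping gene.

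Of 30 G2 and mitosis genes 29 fell at 500 nM, with a median of -0.669 (adjusted p = 4.57e-28, and adjusted p = 0.0237 with an estimated correlation). PLK1 fell by 1.52 ± 0.07 on the log2 scale, CCNB1 by 1.32 ± 0.05. Of 31 DNA replication and S-phase genes, 6 rose and 10 fell with a median of 0.005, and the list was not called (adjusted p = 0.665). RFC3 (-0.62 ± 0.06) and RRM1 (-0.45 ± 0.05) fell, and CDC45 (0.36 ± 0.05) rose. Among 26 homologous recombination and DNA repair genes, 6 rose, EXO1 most clearly (0.80 ± 0.05), and 5 fell, MSH6 among them (-0.52 ± 0.05), with adjusted p = 0.788 for the list. The DNA replication list had a mean of -0.026 and its test pointed down, and the repair list had a median of -0.002 and a mean of 0.027, with its test pointing up. Of 25 p53 targets 17 rose and 5 fell (adjusted p = 1.19e-11, and adjusted p = 0.00333 with an estimated correlation). CDKN1A rose by 2.95 ± 0.07, and RRM2B, a ribonucleotide reductase subunit gene, fell by 0.66 ± 0.06. Of 24 BCL2-family and apoptosis genes 9 rose, including BBC3 (2.54 ± 0.11) and PMAIP1 (0.85 ± 0.07), and 5 fell, including BIK (-0.64 ± 0.08), with adjusted p = 0.0726 for the list. The BCL2-family list was called higher under total-count scaling (0.0189), with GC trends removed (0.0444) and without a filter (0.0458). In the main design its adjusted p was 0.208 with an estimated correlation.

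NF-kB targets and immediate-early genes were called higher at 500 nM (adjusted p = 1.43e-08 and 7.53e-08), though not with an estimated correlation (adjusted p = 0.0634 and 0.0568). Of 22 NF-kB targets 13 rose, led by the adhesion molecule gene ICAM1 (4.94 ± 0.18) and NFKBIA (1.18 ± 0.06), and CD40 fell (-0.31 ± 0.13), a call lost without DMSO replicate 1 or 2 or 500 nM replicate 1 or 3 (adjusted p = 0.0854 to 0.123), under total-count scaling (-0.17, adjusted p = 0.269) and under 4 other alternatives (0.0506 to 0.059). Of 17 immediate-early genes 15 rose, including JUN (2.79 ± 0.14), JUND (1.70 ± 0.09) and JUNB (1.24 ± 0.10), and DUSP2 fell (-0.76 ± 0.12). Of 19 iron and metal genes 9 rose and 5 fell (adjusted p = 0.00602, and adjusted p = 0.0568 with an estimated correlation). The members that rose included the zinc exporter gene SLC30A1 (2.86 ± 0.16), the metallothionein gene MT1X (2.59 ± 0.18) and the ferritin gene FTH1 (0.75 ± 0.06), and the zinc importer gene SLC39A10 fell (-0.76 ± 0.09). MT1X belongs to a family of similar genes whose reads the counting could split.

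The lists of heat-shock, cholesterol synthesis, MYC target, ribosomal protein, oxidative phosphorylation and glycolysis genes were called lower at 500 nM. With an estimated correlation the first 2 calls held, at adjusted p = 0.0496 each, and the last 4 did not (adjusted p = 0.0736, 0.199, 0.0568 and 0.178). Of 16 heat-shock genes 12 fell, including HSPA8 (-1.29 ± 0.05) and HSP90AB1 (-1.09 ± 0.05), and HSPB1 rose (0.32 ± 0.08, and 0.13 with adjusted p = 0.0854 when GC trends were removed). Of 27 cholesterol synthesis genes 17 fell, including HMGCS1 (-0.80 ± 0.05), and 2 rose, among them SREBF1 (0.59 ± 0.09). Of 30 MYC targets and ribosome biogenesis genes 25 fell, including NCL (-0.76 ± 0.05), and MYC itself rose (0.27 ± 0.05). Of 33 ribosomal proteins 27 fell, including RPL3 (-0.96 ± 0.06). Of 30 oxidative phosphorylation genes 28 fell, including ATP5A1 (-0.84 ± 0.05). Of 17 glycolysis genes 14 fell, including LDHA (-1.11 ± 0.05) and ALDOA (-0.72 ± 0.05), and 3 rose. Ribosomal protein, HSPA8 and HSP90AB1 genes have processed pseudogenes that can share their reads.

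**Figure D2:**
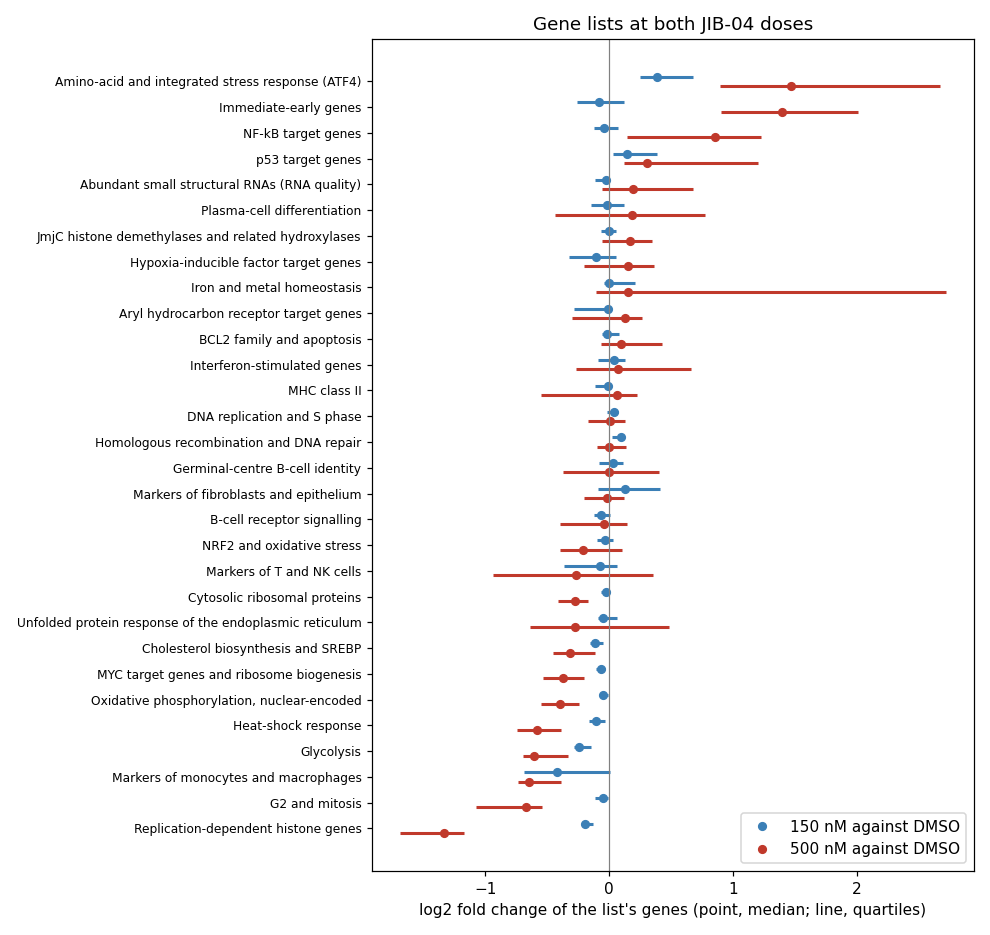
Median (points) and quartiles (lines) of the log2 fold changes of each gene list's tested members at 150 nM (blue) and 500 nM (red) against DMSO. The ATF4 list has medians of 0.389 and 1.472, and the histone list has medians of -0.195 and -1.334.

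Of 25 Jumonji demethylases and related hydroxylases, 12 rose and 4 fell at 500 nM, and the list was not called (adjusted p = 0.0891, and 0.0328 under total-count scaling). In the main design its adjusted p was 0.484 with an estimated correlation. KDM6B, an H3K27 demethylase gene, rose by 1.75 ± 0.10, KDM4A by 0.34 ± 0.06 (adjusted p = 6.31e-05), KDM4C by 0.23 ± 0.06 (adjusted p = 0.00249) and JMJD1C by 0.47 ± 0.06, and KDM3B fell (-0.27 ± 0.05). KDM4B (0.01 ± 0.09) and KDM5A (-0.01 ± 0.05) were not called, though KDM5A was called higher under total-count scaling (0.13). The transcription factor gene IRF4 rose from 246 to 451 CPM (0.88 ± 0.05), while BCL6 (0.04 ± 0.05), BCL2 (-0.03 ± 0.05) and PRDM1 (-0.45 ± 0.26) were not called. Under total-count scaling BCL6 (0.18) and BCL2 (0.11) were called higher.

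Of 19 germinal-centre genes 6 rose at 500 nM, including BACH2 (0.61 ± 0.05), and 9 fell, including ELL3 (-1.02 ± 0.05) and MME (-0.57 ± 0.05). Of 16 plasma-cell genes 7 rose, including TNFRSF17 (1.38 ± 0.08) and XBP1 (1.63 ± 0.12), and 5 fell, including MZB1 (-0.92 ± 0.06). Of 21 B-cell receptor signalling genes 3 rose, including PLCG2 (0.49 ± 0.06), and 10 fell, including BTK (-0.72 ± 0.05) and VAV1 (-0.65 ± 0.06). Of 6 MHC class II genes 2 rose and 2 fell, HLA-DMA among the latter (-1.31 ± 0.13). None of these 4 lists was called, at adjusted p = 0.417, 0.343, 0.0823 and 0.662. The B-cell receptor list was called lower with GC trends removed (adjusted p = 0.0203), without a filter (0.0445) and without the 20 most abundant genes (0.0323). In the main design its adjusted p was 0.208 with an estimated correlation. The germinal-centre list had a median of -0.003 and a mean of 0.221, and its test pointed down. The MHC class II list had a median of 0.06 and a mean of 0.14, and its test pointed down.

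The remaining lists were not called at 500 nM. Of 23 hypoxia-inducible factor targets 11 rose, including VEGFA (2.82 ± 0.14), and 3 fell, including PFKFB4 (-1.47 ± 0.21), with adjusted p = 0.0889, and 0.0127 without DMSO replicate 3. Of 21 unfolded protein response genes 7 rose, including SEL1L (1.38 ± 0.05), and 11 fell, including CALR (-1.02 ± 0.05), with adjusted p = 0.565. Of 18 NRF2 and oxidative stress genes 3 rose, including the cystine transporter gene SLC7A11 (1.61 ± 0.07), and 10 fell, including PRDX1 (-0.81 ± 0.04), with adjusted p = 0.25. SLC7A11 is in the ATF4 list too. Of 24 interferon-stimulated genes 8 rose, including IRF7 (1.90 ± 0.14), and 8 fell, including IFI44 (-2.15 ± 0.19), with adjusted p = 0.7. Of 7 aryl hydrocarbon receptor targets 3 rose, including AHR (0.29 ± 0.09), and CYP1A1 fell, with adjusted p = 0.565, a median of 0.129 and a mean of -0.269. Of 8 structural RNAs 4 rose, including TERC (0.68 ± 0.07), and RNU12 fell (-0.49 ± 0.19), with adjusted p = 0.343 for the list, which was called higher with length trends removed (median 0.496, adjusted p = 0.00462). The call of RNU12 was lost without DMSO replicate 2 or 3 or 500 nM replicate 2 or 3 (adjusted p = 0.0703 to 0.176), under total-count scaling (-0.36, adjusted p = 0.117) and with length trends removed (-0.09, adjusted p = 0.708). Among markers of other cells, 2 rose and 4 fell of 12 T- and NK-cell genes, 0 of 5 monocyte genes were called by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom), and 1 fell of 4 fibroblast and epithelial genes, at adjusted p = 0.32, 0.651 and 0.788. Of the T- and NK-cell markers, CD3G (-1.33 ± 0.13) fell and ZAP70 (0.77 ± 0.17) rose. Erythroid markers had 2 tested members, too few for a list test, and no mitochondrially encoded gene was in the table.

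Adjusted over the list alone, the counts at 500 nM differed from those above for 1 more NF-kB target, p53 target, B-cell receptor gene, plasma-cell gene, T- and NK-cell gene and cholesterol gene, 1 more ribosomal protein and 2 more heat-shock genes. Scaling by total counts alone raised the median of all genes at 500 nM from 0.012 to 0.151 on the log2 scale. Under that scaling 5716 genes rose and 2514 fell, so that 69.5% of the called genes were higher instead of 50.7%, and changes smaller than this shift depend on the scaling.

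The third comparison set 500 nM against 150 nM. ATF4 targets rose with the higher dose, including SESN2 (2.52 ± 0.07), PPP1R15A (2.58 ± 0.08) and WARS (1.74 ± 0.06), and histone genes fell, including HIST1H1B (-1.81 ± 0.05). KLHDC7B (5.19 ± 0.35), FAM129A (5.02 ± 0.22) and FERMT2 (4.57 ± 0.25) had the largest increases, and FCRL2 (-2.22 ± 0.09), LGALS14 (-2.20 ± 0.20) and CAMP (-2.15 ± 0.15) the largest decreases. In total 3577 genes rose and 3444 fell, 46.5% of the genes tested. Of the 30 lists, 8 were called higher and 8 lower. With an estimated correlation the calls held for 5 lists that rose (ATF4, p53, immediate-early, NF-kB, and iron and metal genes) and 4 that fell (histones, G2 and mitosis, heat shock, and oxidative phosphorylation). The other lists called higher were BCL2-family, hypoxia-inducible factor and Jumonji genes, with adjusted p = 0.194, 0.251 and 0.346 with an estimated correlation. The other lists called lower were cholesterol synthesis, MYC targets, ribosomal proteins and glycolysis, with adjusted p = 0.0817, 0.085, 0.194 and 0.346 with an estimated correlation. The call of BCL2-family genes was lost without DMSO replicate 2 or 150 nM replicate 3 (adjusted p = 0.0525 and 0.0609), and that of Jumonji genes without 500 nM replicate 1 (0.0517). With length trends removed both calls were lost (0.0563 and 0.0597) and structural RNAs were called higher (0.001). With GC trends removed, B-cell receptor genes were called lower (0.0354). KDM6B (1.59 ± 0.10) and IRF4 (0.84 ± 0.05) also rose with the higher dose.

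Over the 3 groups together, 7579 genes changed. Of the 144 genes higher at 150 nM, 143 were higher at 500 nM too, and 142 of those rose significantly from 150 to 500 nM. Of the 48 genes lower at 150 nM, 47 were lower at 500 nM. The exceptions, named after their values were seen, were ZWILCH (0.24 ± 0.06 at 150 nM and 0.13 ± 0.06 at 500 nM) and AK4 (0.19 ± 0.21 at 500 nM). The call of ZWILCH at 150 nM was lost without each library but DMSO replicate 3 and 150 nM replicate 1 (adjusted p = 0.0582 to 0.349), by limma-voom (0.0633) and in the fit of the 6 libraries compared (0.117). At 500 nM ZWILCH was called higher under total-count scaling (0.27, adjusted p = 0.000434) and with GC trends removed (0.16, adjusted p = 0.00227). It was also called there with the filter of 1 CPM (adjusted p = 0.0497), in the fit of the 6 libraries compared (0.038) and without 150 nM replicate 1 (0.045). AK4 was called higher at 500 nM without DMSO replicate 3 (0.52, adjusted p = 0.0242). Independent lists of these sizes would share 37.9 and 12.3 genes, a reference that leaves out the shared DMSO libraries, so part of the overlap may come from sharing them. The median change of the genes higher at 150 nM was 0.5 there and 1.73 at 500 nM. Across 12572 genes of at least 1 CPM, the log2 fold changes of the 2 doses correlated at r = 0.692 across genes, which are not independent replicates. Both doses share the DMSO libraries, and 20 simulations of unchanged groups gave a mean r of 0.515. The covariance was 0.0981, against 0.0106 in the simulations, a difference of 0.0875. Log2 fold changes had the same sign at both doses for 69.35% of genes, against 66.9% in the simulations. The simulated groups hold no effects to call, so their shared calls (means of 0 higher and 0.1 lower) are no reference for the overlap. With separate DMSO libraries for the doses, 1 for one and 2 for the other, an alternative chosen after the data were seen, the 6 ways gave r = 0.489 to 0.572, a covariance of 0.0893 to 0.107 and the same sign for 57.8% to 67% of genes. Separate controls were not simulated. The simulated values above come from shared DMSO libraries, so they are no reference for these.

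**Figure D3:**
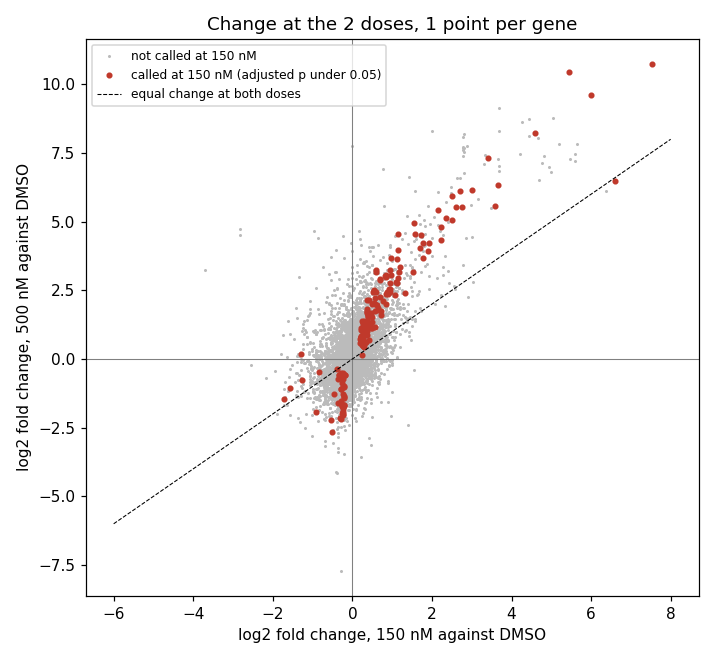
Log2 fold changes against DMSO of 15089 genes at 150 nM (horizontal axis) and 500 nM (vertical axis), 1 point per gene. Red points are the 192 genes called at 150 nM, of which 143 higher and 47 lower genes were called in the same direction at 500 nM.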

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

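Chosen after the results were seen were the 3 tests of the histone pattern and the test of exchanged labels. The tests of GC content and length were set down before their results were seen. A tested difference between the doses whose values had opposite signs singled out 2 results. AK4 fell at 150 nM and was higher at 500 nM than at 150 nM by 1.48 on the log2 scale (edgeR adjusted p = 2.63e-05). Hypoxia-inducible factor targets were called lower at 150 nM (median -0.107, adjusted p = 0.000555) and higher at 500 nM than at 150 nM (median 0.272, adjusted p = 0.000767), but the adjusted p was 0.396 and 0.251 with an estimated correlation, and the first call was lost without DMSO replicate 3 (adjusted p = 0.1).

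The split of the 6 DMSO and 150 nM libraries that exchanges DMSO replicate 3 with 150 nM replicate 1 called 985 genes, against 192 for the labelled split, and only 9 genes were called by both. Exchanged labels are argued against by the ATF4 list. Its mean centred log2 CPM was -0.84 in DMSO replicate 3, beside -0.85 and -0.81 in the other DMSO libraries. In 150 nM replicate 1 it was -0.28, beside -0.32 and -0.24 in the other 150 nM libraries. The hypoxia-inducible factor list (0.08 and -0.23 in this pair) went with the labels too. The ribosomal protein list went the other way. It was 0.06 in DMSO replicate 3, beside 0.04 and 0.06 in 150 nM replicates 2 and 3. In 150 nM replicate 1 it was 0.11, beside 0.14 in each other DMSO library. The histone list (0.44 and 0.41 in this pair) lay between the groups. In the glycolysis list DMSO replicate 3 (0.25) lay with DMSO, and 150 nM replicate 1 (0.08) lay between. A difference in GC bias between libraries is a candidate explanation, since removing each library's trend on GC content left 15 of 1010 calls among the 14414 genes with a value, while removing the trend on transcript length left 883. The same removal raised the calls of the labelled split from 195 to 361. What made the libraries differ in GC trend stays open, since the labels give no batch, and no biological explanation was tested.

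Histone genes fell together at 500 nM, with a median log2 fold change of -1.334. Loss of short RNAs as the whole cause is argued against by 553 other genes with short transcripts, which had a median of -0.18 (quartiles -0.44 and 0.1), although 224 small nucleolar RNA genes had a median of -0.6. A lower yield of RNA without a poly(A) tail stays open, since 8 structural RNAs had a median of 0.19 and a lowest value of -0.49, while the small nucleolar RNA genes, which lack this tail too, fell (quartiles -0.89 and -0.26). Depletion of ribosomal RNA from total RNA does not itself select on this tail, so the design gives no direct reason for such a loss. A smaller share of dividing cells stays open, since the DNA replication list had a median of 0.005 (quartiles -0.17 and 0.13), while 29 of 30 G2 and mitosis genes fell (median -0.669) and CDKN1A rose (2.95). An effect of the dose on histone transcripts or on passage through S phase stays open as a hypothesis that these data do not test.

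For the comparison of 150 nM with DMSO, 2 of the 10 splits called as many genes as the labelled one (192, highest other 985). For 500 nM against DMSO it was 1 of 10 (7843, highest other 0), and for 500 nM against 150 nM 1 of 10 (7021, highest other 0). These 10 splits are too few for a share under 0.05. For the test over 3 groups, 3 of 100 drawn splits of the 280 called at least 7579 genes (highest other 8909). The 4 drawn splits that kept the 500 nM libraries together, the labelled one included, called 7174 to 8909 genes and the other 96 called 0. The share of 3 in 100 therefore rests on the separation of the 500 nM libraries. It does not bear on the grouping of the DMSO and 150 nM libraries, for which 2 of the other 3 such splits called more genes than the labelled one. The labels do not say whether the libraries of a group are separate cultures, so this share does not exclude chance.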

How the results depend on the processing

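Counts for 500 nM against DMSO, 500 nM against 150 nM and any group stayed within 1.5 times under each tool, filter, scaling and left-out library, except that total-count scaling lowered the genes that fell to 2514 and 2137. Leaving out 1 library gave 7053 to 8230, 6062 to 7199 and 6478 to 8365 genes. At 150 nM the calls were 320 (243 higher, 77 lower) without a filter, 291 (80 lower) with DESeq2, 101 (82 and 19) with the 6 libraries alone and 361 (250 and 111) with GC trends removed, an alternative chosen after the data were seen. Without 1 library they were 98 to 545, with 85 to 368 higher and 13 to 177 lower. The cause of these differences was not tested beyond the GC trend. Requiring 2-fold left 41, 1545 and 1165 genes in the 3 comparisons. With an estimated correlation the lists called were 0 lower at 150 nM, 2 higher and 4 lower at 500 nM, and 5 higher and 4 lower for 500 against 150 nM. With fry they were 2 lower at 150 nM, 10 higher and 14 lower at 500 nM, and 14 lower for 500 against 150 nM. Scaling by total counts alone turned KDM5A (0.13 against DMSO, 0.11 against 150 nM) and BCL2 (0.11 in both), which were not called, to higher. The correlation of the doses was 0.618 to 0.709 without 1 library, and 0.531 on average with separate DMSO libraries for the 2 doses (chosen after the data were seen). The covariance changed little, from 0.0981 to 0.0954 on average. The drop in r therefore came mainly with a wider spread of the log2 fold changes, where each dose had fewer control libraries. What else contributed was not tested. Deviations of same-numbered libraries correlated at -0.052 to 0.104, and those of other-numbered libraries at -0.083 to 0.035. Between DMSO and 150 nM, each same-numbered pair (0.104, 0.013 and 0.07) was above every other-numbered pair (-0.083 to 0.008). The labels do not say that replicate numbers mark a shared culture or day, so a shared replicate effect stays open. With the replicate block 308 genes (99 lower) were called at 150 nM. Thinned to the smallest library total, an alternative chosen after the data were seen, the 3 comparisons called 192, 7622 and 6769 genes. What deeper libraries would add was not tested.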

Other observations

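The tests of the olfactory receptor genes were chosen after their totals were seen, and the other tests were set down before. Genes with few counts tended to be higher at 500 nM and abundant genes lower. The 10% of genes with the lowest mean expression had a median log2 fold change of 0.37 and the 10% with the highest had -0.23, with Spearman's rho = -0.221 across genes, which are not independent replicates. Depth is argued against as the whole cause, since rho was -0.216 with every library thinned to the smallest total. The median of the lowest 10% was then 0.29. A few abundant genes are argued against too, since rho was -0.22 without the 20 most abundant. The filter can keep a rare gene through the group where it is high, and what this adds to the trend was not tested. No rise of background reads was seen in 395 olfactory receptor genes under 1 CPM. Their summed CPM overlapped between DMSO (4.66 to 6.7) and 500 nM (4.88 to 6.43), with a log2 ratio of -0.13 (0.01 when scaled by total counts alone). The DMSO libraries alone spread over a range that holds the 500 nM values. Such an overlap could occur even with a small rise of background reads, so it does not exclude one. An effect of the dose stays open as a hypothesis.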
